A study of Homo sapiens with 8 samples.

How the data were processed

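Gene expression was measured with 2-colour Agilent oligonucleotide arrays in TMD8 and HBL1, established cell lines of activated B cell-like (ABC) diffuse large B cell lymphoma. Per the labels, cells carried retroviral vectors with doxycycline-inducible short hairpin RNAs (shRNAs), and 200 ng/mL doxycycline was given for 1 or 2 days. Each of the 8 arrays set the Cy5-labelled RNA of cells with a TLR9 hairpin, C4 or D7, against the Cy3-labelled RNA of cells of the same line and day with the control hairpin shSC4. The 8 arrays thus cover 2 lines, 2 hairpins and 2 days once each, in 1 dye orientation. Groups were the line and hairpin pairs, with 2 arrays each, 1 per day. Nothing in the labels says that arrays came from separate cultures, so p-values measure the spread between these samples, which may be technical.

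Spot intensity in both channels was deposited unnormalized, as mean pixel brightness with the local median background, per the file headers, which name Agilent Feature Extraction 10.1.1.1 and array design 014850. The same files hold processed intensity values that, per the file headers, were background-subtracted, spatially detrended and dye-normalized with linear and LOWESS steps. The deposited log10 ratio of each spot is Cy5 over Cy3 of those processed signals, per the file headers. The authors' deposited value table is in log2, and its values differed from the log2 ratio of processed Cy5 over Cy3 by at most 5e-04 on every array. This settles its scale and direction, and it was not centred again, with column medians from -0.13 to -0.02. Reads, aligners and depth do not apply to arrays, and their number, 8, limits the precision.

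From the scanned intensities, the background was corrected with normexp (offset 50), and log2 ratios were normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Of 45015 spots per array, 1639 were control spots and were left out of the tests. Spots with outlier flags were set to missing, and no spot was saturated (0 on each array). The 43376 remaining spots covered 41000 probes after replicate spots were averaged. A probe was kept where it was well above background in either channel on at least 4 arrays, which left 29635 probes. Between 66.5% and 82.7% of probes were well above background in either channel on an array. For a gene with several probes the probe with the highest mean intensity was used, which gave 21170 genes or unnamed targets. Among 5014 other probes of genes past the threshold on average, 78.2% had the sign of the probe used.

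Probe names were updated through a RefSeq gene table of GRCh38.p14, used for names only. The accession named 27294 probes, the symbol 2383 and an older symbol 454, and 10869 kept the name in the files. Probe coordinates are those of the files, on hg19. No annotation of that build was used here, so exon or untranslated region is not given.

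Log2 ratios were fitted with limma (lmFit and eBayes) in 1 model over all 8 arrays with line, hairpin and day as additive terms, which left 4 residual and 4.58 prior degrees of freedom. The tests were the mean ratio against 0, the mean ratio of each line against 0, and the differences TMD8 minus HBL1, C4 minus D7 and day 2 minus day 1. The control RNA was hybridised in Cy3 alone, so a ratio against 0 leaves out the spread of the control. A dye effect of a gene is confounded with knockdown in the mean and in each line. It cancels in the 3 differences only where it is the same on all arrays, which was not tested. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The median standard error of a gene was 0.03 for the mean, 0.05 for a line and 0.07 for a difference, on the log2 scale. Values are log2 of knockdown over control, so that 1 is a doubling, and errors of means are the SD over arrays. For a gene at background in 1 channel, a fold is given as a lower limit against the lowest signal well above background, after loess and Aquantile scaling, and is open to dye bias.

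The 27 gene lists were written before the data were examined, as were the design, the rule for named genes and the alternatives, apart from those stated otherwise. Lists were tested with camera (preset correlation 0.01), and with an estimated correlation and fry beside it, with Benjamini-Hochberg adjustment over lists within a comparison. Lists share members, and camera compares a list with the other genes on the array. Named genes were TLR9, the 10 largest rises and falls of the mean among genes past the threshold with 1 sign on all 8 arrays, the 5 largest in each direction in each line, and the 6 largest in each direction per difference with 1 sign in the 4 matched pairs. Where fewer passed, genes with the smallest p filled the places. Up to 4 members of a called list and up to 2 of another were named by the size of the moderated statistic. XIST and Y-linked genes were not named, and some list members that the rule would name are not reported here.

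Slide and scan followed the cell line, so that slide and line cannot be told apart. Each slide held both hairpins and both days, and their differences were also fitted within each slide. The positions on a slide held C4 day 1, C4 day 2, D7 day 1 and D7 day 2 in the same order on both slides, so position cannot be separated from the combination of hairpin and day. Replicate numbers followed accession order, which here is the order of days, and pair nothing beyond line and day. Arrays of 1 line and day share a control label, which gives 4 control labels, and line and day were therefore tried as a block.

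The model was tested on simulated data with 200 changed genes among 20883. For the mean, 56.7% of genes changed by 0.2 and 98.5% of those changed by 0.5 on the log2 scale were recovered, with 11 false calls of 181. For the difference between lines 73.1% of changes of 0.5 and 98.5% of changes of 1 were recovered, with 8 false calls of 122. For the hairpins these shares were 79.1% and 93.9%, with 7 false calls of 125. For the days they were 64.2% and 93.9%, with 8 false calls of 116. A list shifted by -0.2 was called (camera adjusted p = 2.48e-47), with 0 of the 26 other lists. The simulated genes were independent of each other, so this cannot show how often lists with correlated members are called falsely. The simulated arrays were also independent, with no shared control and no dye effect. False calls that these could cause in the real data were thus not measured. Alternatives changed the background correction, normalization within and between arrays, values used, filter, probe per gene, spread estimate, array weights, model terms, control block and set test, and left out each array in turn. A correction for probe base composition was added after seeing the data. The statmod version was 1.5.0.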

Results

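TLR9 knockdown was profiled on 8 arrays of TMD8 and HBL1 cells, with 4 arrays per line, 4 per hairpin and 4 per day. TLR9 encodes an endosomal receptor for unmethylated CpG DNA that signals through MYD88. The series asks how B cell receptor signalling differs between lymphomas, and these arrays ask what loss of TLR9 does to gene expression in the ABC form. The SD of the log2 ratios ranged from 0.16 on the TMD8 C4 day 1 array to 0.30 on the TMD8 C4 day 2 array.

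TLR9 itself was lower in knockdown than in control cells on each of the 8 arrays. Its mean log2 ratio was -1.39 ± 0.27 (SD, n = 8). This left 38.3% of the control level (two-sided exact sign-flip permutation p = 0.00781, the smallest that 8 arrays allow). Hairpin C4 left 36% of the control level (log2 ratio -1.47 ± 0.27, SD, n = 4) and D7 left 40.7% (-1.30 ± 0.28, n = 4). The residual level was 44.8% in TMD8 (-1.16 ± 0.13, n = 4) and 32.7% in HBL1 (-1.61 ± 0.12, n = 4). This difference between lines passed the limma test (0.45, adjusted p = 0.00347). The differences between hairpins (-0.18, adjusted p = 0.0824) and between days (0.11, adjusted p = 0.383) did not. The probe, A_23_P132654 for NM_017442, lies on the minus strand of chromosome 3 from 52255221 to 52255280 (hg19).

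**Figure D1:**
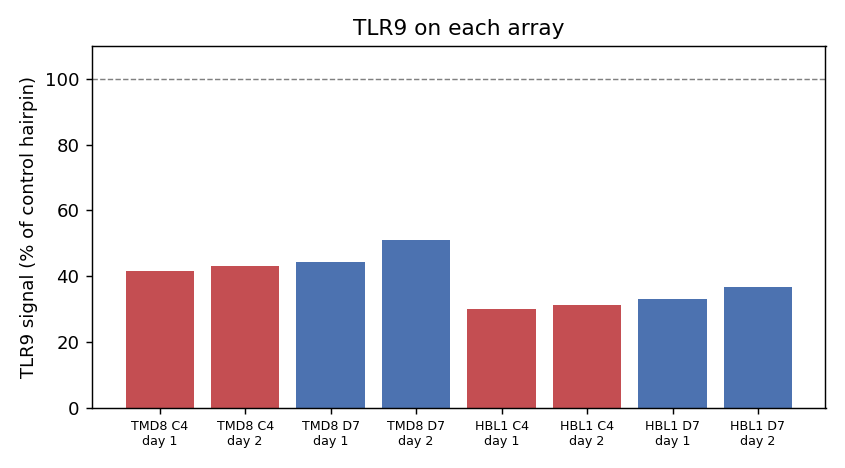
TLR9 level (y axis) on each of the 8 arrays (x axis) as a percentage of the shSC4 control of the same line and day, with 1 bar per array (red C4, blue D7) and the control level as a dashed line. The arrays lie between 30.1% and 51%, with the 4 HBL1 arrays below the 4 TMD8 arrays.

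Over both lines, CD52 and several MHC class II genes were among the largest rises in knockdown over control cells. CD52, a glycoprotein of the lymphocyte surface, rose 2.92-fold (log2 1.54 ± 0.55, SD, n = 8, adjusted p = 2.35e-06). The MHC class II genes HLA-DPB1 (1.14 ± 0.73), HLA-DPA1 (1.04 ± 0.64), HLA-DRB5 (1.03 ± 0.41) and HLA-DRA (1.00 ± 0.57) rose. So did ALDH2, which encodes mitochondrial aldehyde dehydrogenase (1.07 ± 0.37), and ADAP2 (1.05 ± 0.42). GZMB, the serine protease granzyme B, fell by 1.33 ± 0.77 on the log2 scale (adjusted p = 2.35e-06). SGK1, a kinase downstream of PI3K (-1.22 ± 0.60), SOCS3, a feedback inhibitor of cytokine signalling (-1.13 ± 0.52), GPRC5B (-1.06 ± 0.25) and the amino acid transporter gene SLC38A5 (-0.86 ± 0.27) also fell, each on all 8 arrays.

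RNU12, the U12 spliceosomal RNA (1.14 ± 0.54), LGALS9C (1.08 ± 0.57) and CPNE5 (1.01 ± 0.64) completed the 10 largest rises. The other falls were larger with hairpin C4 for NPM3 (-1.21 ± 0.88), GNG5 (-1.14 ± 1.03) and EIF1AX (-0.94 ± 0.62), and larger in TMD8 for VSNL1 (-0.89 ± 0.68). Probes of paralogs such as HLA-DRB5 and LGALS9C can take up RNA of near-identical genes, so their values are uncertain. A second probe of SOCS3 gave -0.27, of ALDH2 0.68 and of LGALS9C 0.58, and 2 other probes of EIF1AX gave -0.97 and -0.44. The CD52 probe A_23_P85800 (NM_001803) lies on the plus strand of chromosome 1 from 26646885 to 26646944, and the GZMB probe A_23_P117602 (NM_004131) on the minus strand of chromosome 14 from 25100236 to 25100295 (hg19).

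In limma, 10621 of 21170 genes passed the threshold for the mean, 6073 higher and 4548 lower, most by small ratios. Of them, 220 changed by over 1.5-fold (175 higher, 45 lower) and 21 by over 2-fold. The number over 1.5-fold depended on the processing. It was 929 with the deposited log ratios, 990 with the authors' value table, 930 with median centring and 151 with the mean of a gene's probes. Among the 220 of the main fit, 193 had 1 sign in all 4 line and hairpin pairs, 55 also differed between hairpins and 65 between lines. With each array centred on its median in place of loess, the median of all genes moved to 0.16 and the count fell to 1376, of which 98% were higher, against 57.2% with loess. The adjusted p of EIF1AX and SLC38A5 was then 0.085 and 0.0832, and with 1 dye orientation a dye effect of a gene remains part of its mean.

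**Figure D2:**
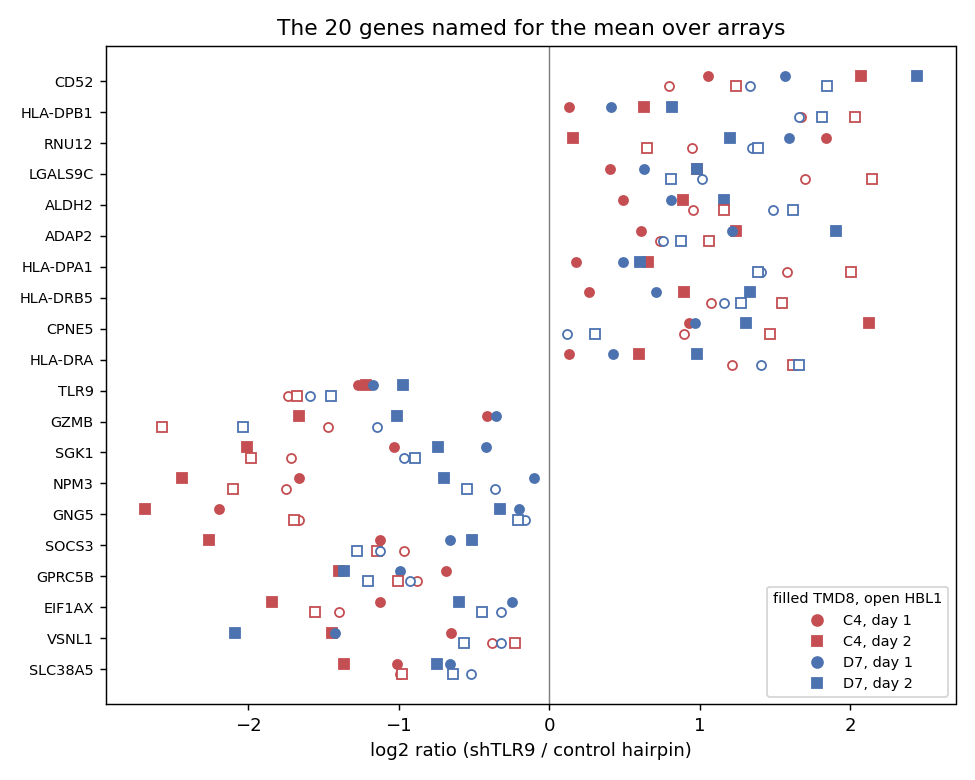
Log2 ratio of knockdown over control (x axis) for the 20 genes named for the mean (y axis), with 1 point per array (red C4, blue D7, circles day 1, squares day 2, filled TMD8, open HBL1). CD52 and TLR9 are at the ends, with means of 1.54 and -1.39, and GNG5 and NPM3 split by hairpin.

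Among the gene lists, MHC class II and antigen presentation rose most, with 27 of 32 measured members higher and 0 lower (28 and 0 adjusted over the list alone). Its mean log2 ratio was 0.52 (camera adjusted p = 6.41e-11, estimated-correlation adjusted p = 0.246), and CIITA, the master regulator of MHC class II transcription, rose by 0.67 and the lysosomal protease gene CTSS by 0.62. Other probes gave 0.15, 0.18, 0.37 and 0.86 for CIITA and 0.15 for CTSS. Type I interferon response genes were higher for 41 of 57 members and lower for 0 (44 and 0 adjusted over the list alone). Their mean was 0.45 (camera adjusted p = 5.7e-07, estimated-correlation adjusted p = 0.661), though the list median was below 0 on both HBL1 D7 arrays (-0.19 and -0.30). They included STAT2 (0.44) and IRF9 (0.52), subunits of the factor ISGF3, and RTP4 (0.74) and BST2 (0.36). B cell identity genes were higher for 22 and lower for 3 of 32 (26 and 3 adjusted over the list alone). Their mean was 0.28 (camera adjusted p = 6.08e-06, estimated-correlation adjusted p = 0.149), with CD79A at 0.93 and MS4A1, which encodes CD20, at 0.37.

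BCR signalling components were higher for 19 and lower for 4 of 31 (19 and 4 adjusted over the list alone). Their mean was 0.21 (camera adjusted p = 0.0072, estimated-correlation adjusted p = 0.297). Beside CD79A, which the B cell identity list also holds, they included the inhibitory receptor gene FCGR2B (0.55) and the phosphatase gene INPP5D (0.46, and 0.19 by a second probe). In the TLR pathway list 20 of 31 members were higher and 3 lower (20 and 3 adjusted over the list alone). Their mean was 0.18 (camera adjusted p = 0.00424, estimated-correlation adjusted p = 0.227), with LY96 (0.69), CD180 (0.59), TASL (0.46) and TLR10 (0.42). Cytosolic ribosomal protein genes were higher for 34 and lower for 1 of 40 (35 and 1 adjusted over the list alone). Their mean was 0.28 (camera adjusted p = 1.05e-11, estimated-correlation adjusted p = 0.166), with RPL28 (0.64), RPS28 (0.61) and RPLP1 (0.60). Other probes of RPL28 and RPS28 gave -0.11 (adjusted p = 0.0337) and -0.05 (adjusted p = 0.143), so these values rest on 1 probe each. Other probes of RPS2 gave -0.439 to 0.212, against 0.672 for the probe used, and of RPL13 -0.125 to 0.615, against 0.55. Those of RPLP0 (0.194 and 0.229) and RPLP1 (0.542) rose. The count of higher members thus depends in part on the probe used.

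MYC targets and ribosome biogenesis genes moved the other way, with 48 of 54 lower and 1 higher (48 and 1 adjusted over the list alone). Their mean was -0.26 (camera adjusted p = 4.71e-18, estimated-correlation adjusted p = 0.403), with falls of TCOF1 (-0.68), DDX21 (-0.57), PA2G4 (-0.53) and NOP16 (-0.52). Other probes gave -0.24 for TCOF1 and -0.23 to -0.25 for PA2G4. ATF4 and amino acid response genes were lower for 21 and higher for 4 of 31 (21 and 4 adjusted over the list alone). Their mean was -0.21 (camera adjusted p = 8.38e-07, estimated-correlation adjusted p = 0.149), with the glutathione-degrading enzyme gene CHAC1 (-0.58), CTH (-0.48) and VEGFA (-0.47, and -0.17 to -0.29 by other probes). SLC7A5, which encodes a leucine transporter, fell by 1.02, while a second probe of it gave -0.10. G1/S and DNA replication genes were lower for 27 and higher for 4 of 45 (28 and 5 adjusted over the list alone). Their mean was -0.12 (camera adjusted p = 6.08e-06, estimated-correlation adjusted p = 0.528), with FEN1 at -0.79 and CDC6 at -0.40. Replication-dependent histones were lower for 12 and higher for 2 of 24 (12 and 2 adjusted over the list alone). Their mean was -0.11 (camera adjusted p = 0.00786, estimated-correlation adjusted p = 0.595), with H2BC12 (-0.93). The list mean was -0.27 in HBL1 (1 higher, 12 lower; camera adjusted p = 3.24e-05) and 0.05 in TMD8 (4 higher, 2 lower; camera adjusted p = 0.564), and H2BC12 was at -1.66 and -0.21. Cholesterol synthesis genes were lower for 13 and higher for 4 of 28 (13 and 4 adjusted over the list alone). Their mean was -0.05 (camera adjusted p = 0.0278, estimated-correlation adjusted p = 0.68), with FASN (-0.44) and SCD (-0.46, and -0.21 to -0.40 by other probes). This call was lost under 6 of 26 alternatives, among them the deposited log ratios and the authors' value table, and turned under 1. By line the mean was -0.09 in HBL1 (camera adjusted p = 0.00377) and -0.02 in TMD8 (camera adjusted p = 0.496). With median centring, under which the median of all genes was 0.16, the means of the G1/S, histone and cholesterol lists turned positive (0.20, 0.25 and 0.24), as did those of the MYC and ATF4 lists (0.11 and 0.04), and none of these calls held. These falls are relative to the other genes of like intensity.

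With an estimated correlation none of the 11 camera calls held (0 lists). Fry, which asks whether members move 1 way on balance, called 13 lists, 9 of these 11 among them, but not interferon (fry adjusted p = 0.0642) or cholesterol synthesis (0.0948). It also called germinal centre genes (0.00408), apoptosis regulators (0.00224) and epithelial or stromal markers (0.000214) higher and immediate early genes (0.00654) lower. The other 16 lists did not pass camera, with adjusted p from 0.0568 for heat shock to 0.865 for the plasma cell list. NF-kB targets split into 18 higher and 22 lower of 55 (19 and 22 adjusted over the list alone; camera adjusted p = 0.387), with IRF4 at -0.66 and TNFAIP2 at -0.84. Markers of T and NK cells (5 higher, 3 lower of 16, and the same counts adjusted over the list alone), myeloid cells (3 and 1 of 14, the same adjusted over the list alone) and epithelial or stromal cells (5 and 2 of 17, 4 and 2 adjusted over the list alone) gave camera adjusted p values of 0.516, 0.58 and 0.377. GZMB belongs to the T and NK cell list and fell, while LCK of that list rose by 0.80.

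**Figure D3:**
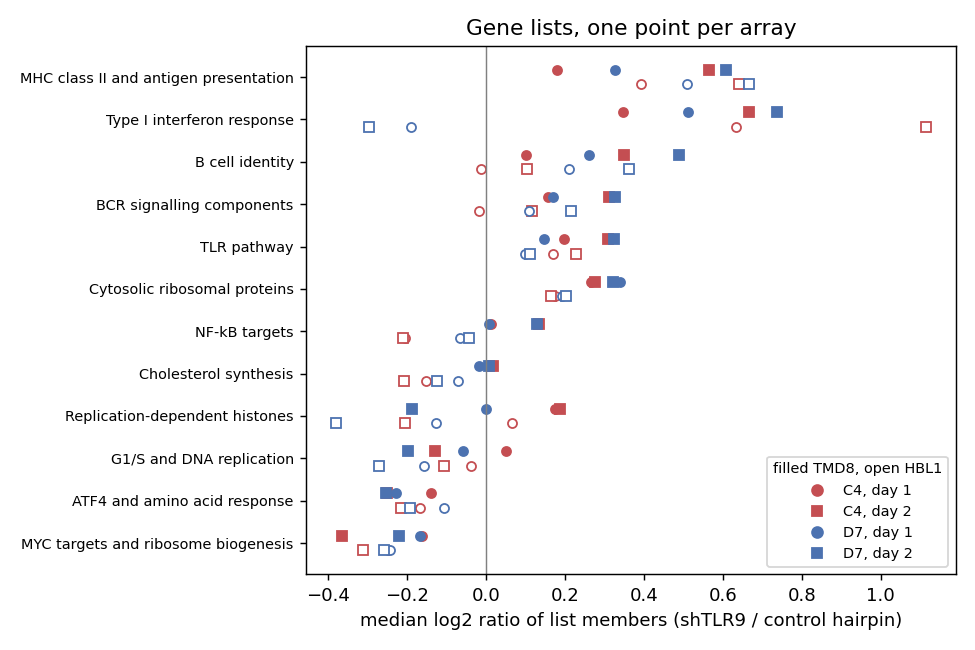
Median log2 ratio of knockdown over control (x axis) over the members of the 11 called gene lists and of NF-kB targets (y axis), with 1 point per array in the same symbols. The interferon list lies at 0.35 to 1.12 on 6 arrays and at -0.19 and -0.30 on the HBL1 D7 arrays.

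Within TMD8, the largest rises were of CD52 (1.78 ± 0.07, mean of 4 arrays with the SE of the model over all 8) and the interferon-induced genes IFIT1 (1.55 ± 0.37), IFIT2 (1.54 ± 0.33), OASL (1.49 ± 0.30) and XAF1 (1.38 ± 0.21). Their limma adjusted p ran from 2.13e-05 for CD52 to 0.0109 for IFIT1. For IFIT1 this SE also takes in the hairpin split in HBL1, where it averaged 1.54 with C4 and -1.03 with D7. The largest falls were of VSNL1 (-1.40), GNG5 (-1.35), ARHGEF10 (-1.33), PHLDA1 (-1.24) and NPM3 (-1.23), with adjusted p of at most 0.000145. Over all arrays a second probe of IFIT2 gave 0.44, against 1.14 for the probe used, and other probes of XAF1 0.615 and 0.847, against 0.896. Other probes of ARHGEF10 gave -0.227 to -0.625, against -0.75, and of PHLDA1 -0.232 to -0.614, against -0.644. Within HBL1, the MHC class II genes HLA-DPB1 (1.79), HLA-DPA1 (1.59) and HLA-DRA (1.48) rose most, with LGALS9C (1.42) and ALDH2 (1.31). GZMB (-1.81), the histone gene H2BC12 (-1.66), TLR9 (-1.61), the chemokine gene CCL4 (-1.53) and SLC7A5 (-1.44) fell most, and adjusted p was at most 0.000323 for these 10 genes of HBL1. A second probe of SLC7A5 gave -0.10 over all arrays, against -1.02 for the probe used. In limma, 7727 genes passed in TMD8 (4609 higher, 3118 lower) and 7586 in HBL1 (4070 higher, 3516 lower), of which 406 and 355 changed by over 1.5-fold. Those over 1.5-fold numbered 1243 and 1037 with the deposited log ratios and 1431 and 1115 with the authors' value table. They numbered 321 and 260 with the mean of a gene's probes. With median centring, which moved the median of all TMD8 ratios to 0.25, the counts of genes past the threshold fell to 371 (98.9% higher) and 10 (90% higher), and TLR9 in HBL1 was at -1.45 (adjusted p = 0.111). Without TMD8 D7 day 1 or HBL1 C4 day 1 these counts were 4742 in TMD8 and 4946 in HBL1, and with C4 and D7 averaged per line and day 5066 and 4982.

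The lines shared 2453 genes higher in both and 1937 lower in both, against 886 and 518 for independent lists. Mean log2 ratios of TMD8 and HBL1 correlated across genes (r = 0.61), and C4 of 1 line against D7 of the other gave 0.41. Genes are not independent replicates, the lines share no control label, and a dye effect common to all arrays would raise this overlap.

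The test of the difference asks which effects of knockdown depend on the line. The chemokine genes CCL4 and CCL3, induced by B cell receptor and NF-kB signalling, had opposite mean ratios in the lines. CCL4 was at 1.09 in TMD8 and -1.53 in HBL1 (difference 2.62 ± 0.22, SE, 4 arrays per line, adjusted p = 0.00129), and CCL3 at 1.33 and -0.84 (2.18 ± 0.26, adjusted p = 0.00347). In HBL1, CCL3 was at -1.59 with D7 and -0.10 with C4. CCL3L3 (1.66), the histone genes H2BC12 (1.46) and H2AC19 (1.30) and BSPRY (1.32) were also higher in TMD8 relative to HBL1. HLA-DPB1 (-1.30) and HLA-DPA1 (-1.11) rose less in TMD8, and ARHGEF10 was -1.33 in TMD8 and -0.17 in HBL1. DENND3 was -0.76 in TMD8 and 0.34 in HBL1. PTGDR and CR1L were at -1.11 and -1.03 in TMD8. In HBL1 their control signal was well above background on 0 of 4 arrays and their knockdown signal on 1 and 0, so no value is given for HBL1 or for the difference.

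NF-kB targets were higher in TMD8 than HBL1 for 13 of 55 members and lower for 0 (26 and 3 adjusted over the list alone). Their mean was 0.26 (camera adjusted p = 3.28e-05, estimated-correlation adjusted p = 0.37), with TNF (0.99) and LTA (0.84). Immediate early genes of B cell receptor signalling were higher for 10 and lower for 4 of 38 (15 and 5 adjusted over the list alone). Their mean was 0.27 (camera adjusted p = 0.00157, estimated-correlation adjusted p = 0.358), with DUSP5 (1.14) and CD69 (0.97). Histones were higher for 11 and lower for 0 of 24 (12 and 0 adjusted over the list alone). Their mean was 0.32 (camera adjusted p = 2.09e-07, estimated-correlation adjusted p = 0.449), with H1-2 at 1.06. MHC class II and antigen presentation genes were lower in TMD8 than HBL1 for 9 and higher for 0 of 32 (14 and 2 adjusted over the list alone). Their mean was -0.25 (camera adjusted p = 6.07e-06, estimated-correlation adjusted p = 0.553), with HLA-DRA at -0.94 and HLA-DOA, whose probes differed, at -0.60, but this mean was 0.05 with median centring.

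Ribosomal protein genes were higher in TMD8 for 8 and lower for 0 of 40 (10 and 0 adjusted over the list alone). Their mean was 0.11 (camera adjusted p = 0.000134, estimated-correlation adjusted p = 0.553). The p53 targets were higher for 4 and lower for 0 of 29 (7 and 0 adjusted over the list alone). Their mean was 0.15 (camera adjusted p = 0.00162, estimated-correlation adjusted p = 0.751), with the cell cycle inhibitor gene CDKN1A at 0.81 and AEN at 0.44. Camera also called interferon genes (mean 0.30, adjusted p = 0.0168, 1 member past the threshold) and heat shock genes (mean 0.08, adjusted p = 0.0291, 4 higher and 1 lower of 24) higher in TMD8, and called unfolded protein response genes lower (mean -0.06, adjusted p = 0.0291, 1 member past the threshold). Each of these 3 lists had an estimated-correlation adjusted p = 0.751. The interferon difference came from D7 (medians of 0.61 in TMD8 and -0.22 in HBL1), as with C4 the list was higher in HBL1 (0.87) than TMD8 (0.53), and 34 members passed for the interaction of line and hairpin. All 3 calls were lost without any 1 of the 4 D7 arrays and with fry (each under 6 of 26 alternatives). With median centring the mean of the unfolded protein response list was 0.19. Counts adjusted over the list alone were 1 and 0 for interferon, 7 and 2 for heat shock and 0 and 1 for the unfolded protein response.

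In all, 1503 genes differed between lines in limma, 863 with a higher and 640 with a lower ratio in TMD8, and 170 were past the threshold in opposite directions in the lines. Each line was on its own slide and scan, so line and slide cannot be told apart. The count was 3263 with the line and day block but 460 with C4 and D7 averaged per line and day. The block correlation was negative (-0.28), which lowers the error of this test. The count was 915 with offset 10, 687 with the deposited log ratios, 743 with the authors' value table, 570 with no hairpin and day terms, and 1 (CCL4) with median centring. It was 604 to 1067 without single arrays, over 1.5 times lower without TMD8 D7 day 1 (604), TMD8 D7 day 2 (810), HBL1 C4 day 2 (827), HBL1 D7 day 1 (856) or HBL1 D7 day 2 (730).

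**Figure D4:**
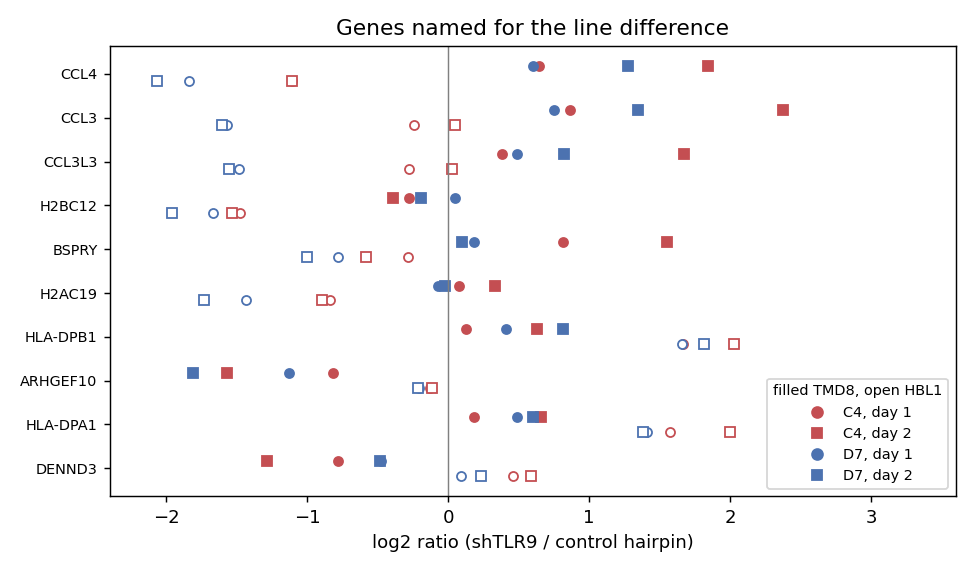
Log2 ratio of knockdown over control (x axis) for the genes named for the difference between TMD8 and HBL1 other than PTGDR and CR1L (y axis), with 1 point per array (filled TMD8, open HBL1, red C4, blue D7, circles day 1, squares day 2). CCL4 averages 1.09 in TMD8 and -1.53 in HBL1, and HLA-DPB1 averages 0.50 and 1.79.

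The comparison of hairpins asks which effects belong to 1 of the hairpins. GNG5, a G protein gamma subunit gene, averaged -2.06 with C4 and -0.23 with D7 (difference -1.84 ± 0.14, SE, 4 arrays per hairpin, adjusted p = 0.000786), and NPM3, a histone chaperone gene, -1.99 and -0.43 (-1.56 ± 0.10, adjusted p = 0.000298). BNIP3, a mitophagy receptor gene (C4 -1.56, D7 0.03), SUMO3, a ubiquitin-like modifier gene (-1.43, 0.07), LAMP2, a lysosomal membrane protein gene (-1.33, 0.11), and CNOT7, a deadenylase subunit gene (-1.35, 0.04), were low with C4 and near the control with D7. 2 other probes of LAMP2 averaged 0.10 and -0.02 over all arrays, against -0.61 for the probe used, and a second probe of SUMO3 -0.24, against -0.68. EMB (1.01 ± 0.09, adjusted p = 0.00126) and CASK (0.84 ± 0.08) were higher with C4 than D7. USP30-AS1 (1.12, adjusted p = 0.0499), ADM (adjusted p = 0.0458), CCL3 (1.03, adjusted p = 0.0499) and DISP2 (0.94, adjusted p = 0.0459) lay near the threshold and lost it under 19, 14, 16 and 15 of 24 alternatives. The ADM control signal was not well above background in TMD8, where knockdown cells were at least 1.27-fold higher.

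Within the TMD8 slide the difference was -2.18 for GNG5, -1.71 for BNIP3 and 0.84 for EMB, and within the HBL1 slide -1.49, -1.46 and 1.18. By list, histones were higher with C4 for 5 and lower for 0 of 24 (15 and 0 adjusted over the list alone). Their mean was 0.23 (camera adjusted p = 6.54e-09, estimated-correlation adjusted p = 0.361), with 0.26 within TMD8 and 0.19 within HBL1. G1/S genes were higher for 8 and lower for 2 of 45 (13 and 2 adjusted over the list alone). Their mean was 0.09 (camera adjusted p = 4.76e-05, estimated-correlation adjusted p = 0.82), with 0.06 within TMD8 and 0.13 within HBL1. G2/M genes were higher for 4 and lower for 0 of 40 (12 and 3 adjusted over the list alone). Their mean was 0.10 (camera adjusted p = 0.000155, estimated-correlation adjusted p = 0.82), with 0.13 within TMD8 and 0.08 within HBL1. MKI67 was at 0.41 and CCNB2 at 0.31. B cell identity genes were lower with C4 for 7 and higher for 0 of 32 (12 and 0 adjusted over the list alone). Their mean was -0.19 (camera adjusted p = 0.000155, estimated-correlation adjusted p = 0.361), with -0.13 within TMD8 and -0.25 within HBL1. BCR components were lower for 8 and higher for 1 of 31 (12 and 1 adjusted over the list alone). Their mean was -0.15 (camera adjusted p = 0.000634, estimated-correlation adjusted p = 0.361), with -0.11 within TMD8 and -0.19 within HBL1. KLF2 was at -0.71 and CD79A at -0.46.

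The interferon list was higher with C4 by a mean of 0.49 (camera adjusted p = 3.18e-09, estimated-correlation adjusted p = 0.82), with 0 of 57 members past the threshold (0 adjusted over the list alone). The difference was -0.15 within TMD8, with 0 members past the threshold, and 1.13 within HBL1, with 51. Unfolded protein response genes were lower with C4 for 2 and higher for 0 of 29 (8 and 2 adjusted over the list alone). Their mean was -0.10 (camera adjusted p = 0.0132, estimated-correlation adjusted p = 0.82), with -0.02 within TMD8 (camera adjusted p = 0.736) and -0.19 within HBL1. With median centring the means of the unfolded protein response, BCR component and B cell identity lists turned to 0.11, 0.08 and 0.006.

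In limma, 1412 genes differed between hairpins, 655 higher and 757 lower with C4, with 707 within TMD8 and 1210 within HBL1. Log2 ratios of C4 and D7 within a line correlated across genes with r = 0.49 on different days (covariance 0.0283), where no control label is shared. On the same day r was 0.54 (covariance 0.0327), where a simulation of shared controls with no effect gave r = 0.50 and a covariance of 0.00818. The simulation gave control and knockdown RNA equal spread, which fixes its r near 0.50. The real share of the control in the spread was not estimated. In HBL1 the SD of the log2 difference between control channels was 0.145 and 0.177 within a day and 0.124 to 0.189 between days. In TMD8 it was 0.122 and 0.254 within a day and 0.133 to 0.266 between days. The label thus may not mark which arrays share control RNA. A dye effect or an effect of the control hairpin common to all arrays would also raise r on different days. The count was 750 with offset 10, 442 with the deposited log ratios (33.7% higher with C4, against 46.4%), 363 with the authors' value table (33.1% higher), 803 with the line and day block, 2415 with an interaction of line and hairpin, and 0 with median centring (limma, 354 at an unadjusted p under 0.05). It was 374 to 885 without single arrays, over 1.5 times lower for each of the 8.

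**Figure D5:**
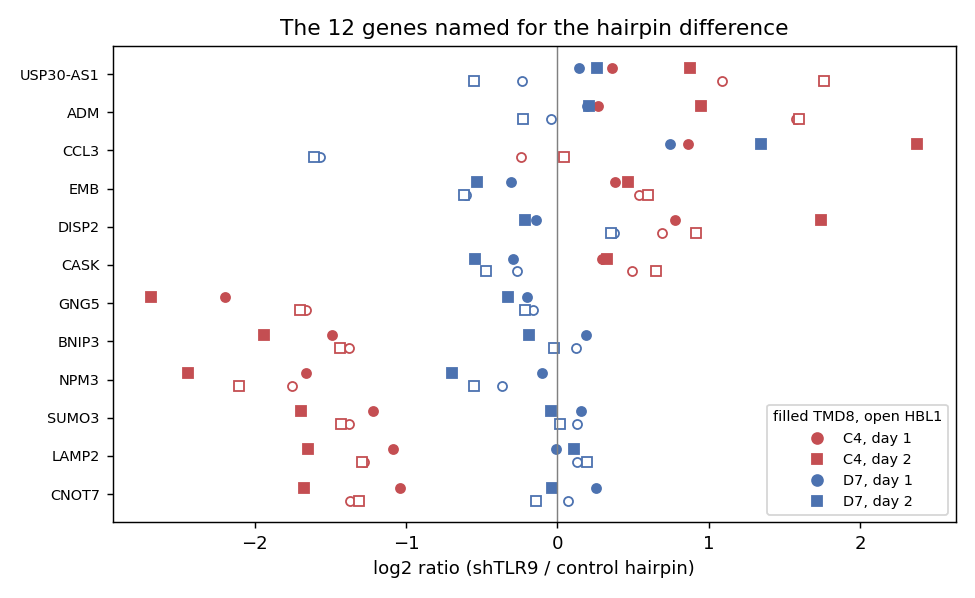
Log2 ratio of knockdown over control (x axis) for the 12 genes named for the difference between hairpins (y axis), with 1 point per array (red C4, blue D7, circles day 1, squares day 2, filled TMD8, open HBL1). BNIP3 averages -1.56 with C4 and 0.03 with D7 over both lines.

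Between day 1 and day 2 of induction, no gene passed the threshold in limma (0 of 21170, with 2998 at an unadjusted p under 0.05). The GZMB day difference came closest, at -0.98 for day 2 minus day 1 (adjusted p = 0.0618). It passed with the filter on all 8 arrays (0.0416), with a trended robust spread (0.0159) and with the line and day block (0.00769). The block correlation was negative, which lowers the error of that last test. The genes next in rank, all at adjusted p = 0.216, included CD52 (0.71), UCP2 (0.60), LGALS1 (0.58), FLOT2 (0.47), SLC37A1 (0.39) and LRP10 (0.36) on the higher side. The lower side held PHLDA1 (-0.70), PIR (-0.52), XPOT (-0.41), DDIAS (-0.36) and CCNQ (-0.31). By list, camera called MHC class II genes higher on day 2 (mean 0.26, adjusted p = 2.71e-14, 20 higher and 0 lower of 32 adjusted over the list alone). It called G1/S genes lower (-0.13, adjusted p = 2.17e-11, 0 higher and 6 lower of 45 adjusted over the list alone). Both lists had 0 members past the threshold over all genes and estimated-correlation adjusted p = 0.191 and 0.212.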

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

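The tests of a dye effect on genes changed by over 1.5-fold, of deeper knockdown with C4, of weaker knockdown in HBL1 with D7, of exchanged labels and of whole line and day sets were chosen after the result was seen.

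The first pattern is that 10621 of 21170 genes passed for the mean, mostly by small ratios. Among 100 sign patterns of the 8 arrays, 1 (the real one) gave as many, and the highest other gave 4328, by reversing TMD8 C4 day 1 against the rest, so chance is excluded for the mean if the arrays are independent (see the sets below). Probe base composition explained 0.812% of the variance of the mean ratio, which argues against a dye effect that follows it. Of the 220 genes over 1.5-fold, 45.9% (95% interval 39.5 to 52.5) also differed between lines or hairpins, against 17.8% of the others. For those that differed, this argues against a common dye effect as the only source. The interval takes the 220 genes as independent, which they are not, so it does not measure the spread between samples. For the 119 of them with no such difference and for the small ratios, a dye effect or an effect of the control hairpin shared by all arrays stays open beside loss of TLR9, since dyes were not swapped.

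The second pattern is the 107 genes lower with C4 than D7 in both lines, among them BNIP3, SUMO3 and CNOT7. They were picked from the 757 genes past the threshold as over 1.5-fold lower with C4 and lower in all 4 matched pairs. Their median was -0.55 with C4 and 0.21 with D7 in TMD8, and -0.59 and 0.16 in HBL1. TLR9 was lower on both C4 arrays than on both D7 arrays of each line, by 0.044 or more, so deeper TLR9 knockdown and the hairpin cannot be told apart within a line. With the same hairpin TLR9 was 0.454 lower in HBL1 than TMD8, yet the median difference of these genes was 0.033 (95% interval over genes -0.014 to 0.076). Genes are not independent replicates, so this interval does not measure the spread between samples. Between hairpins the median difference was -0.701, a size that the cut used to pick the genes enlarges. The difference between lines was not selected and lay near 0. It would argue against deeper knockdown only if both lines responded alike. That is not known, as 1503 genes differed between lines and each line had its own slide. Deeper knockdown thus stays open. A short match of the hairpin to other transcripts is a candidate explanation that stays open, as the smallest adjusted p for a shared 7-base word was 0.37 with 60 bases searched per gene, and array position, which followed the hairpin, stays open too.

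The third pattern is the interferon list, with median log2 ratios of 0.53 and 0.61 in TMD8 with C4 and D7, 0.87 in HBL1 with C4 and -0.22 in HBL1 with D7, where 44 of 57 members were below 0. The interaction of line and hairpin passed for 113 genes, 34 of them in this list (camera adjusted p = 3.33e-67, estimated-correlation adjusted p = 0.451), and IFIT1 averaged 1.39, 1.72, 1.54 and -1.03 in the 4 pairs. Control RNA accounted for -1.32% and -2.78% of the C4 minus D7 difference in HBL1 on the 2 days, which argues against controls that differed between these arrays. Interferon transcripts in a control common to both hairpins cancel in this difference and stay open. TLR9 fell more on the HBL1 D7 arrays (-1.45 or lower) than on any TMD8 array (-1.27 or higher). This would argue against weaker knockdown only if both lines responded alike, which is not known. Within HBL1, however, TLR9 fell less with D7 (-1.59 and -1.45) than with C4 (-1.73 and -1.68), so weaker knockdown stays open there. Genes lower with C4 in TMD8 were lower with C4 in HBL1 as well (median -0.455), which argues against exchanged labels. An interferon response to 3 of the 4 hairpin transductions, or one lost with D7 in HBL1, may be biological or come from culture, and nothing here separates these.

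Each split test put the split in place of the tested term and kept the other terms. The split by hairpin was thus fitted with no line term in the line test, and so gave fewer genes than in its own test. The split of arrays by line gave 1503 genes, with 359 for the highest of the other 34 splits, that by hairpin (1 of 35 as large). The split by hairpin gave 1412 in its own test, with 579 for the highest other, that by line (1 of 35). Chance is thus excluded for both if the arrays are independent. Arrays of 1 line and day share a control label, and the sign patterns of whole line and day sets for the mean (1 of 8 as large, highest other 311), splits of whole sets by line (1 of 3, highest other 0) and swaps of hairpins within sets (1 of 8, highest other 0) are too few for a share under 0.05. All 35 of 35 splits gave at least as many genes as the 0 by day, which any split must. The highest was 1128 for the split by line, fitted in this test with no day term. For TMD8 and HBL1 alone the 8 sign patterns are too few for a share under 0.05, with 7727 and 7586 genes for the real pattern (1 of 8) and 15 and 32 for the highest other.

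Single arrays stood apart in 3 of 72 sets of values, where chance gives about 1 in 20. They were SOCS3 on TMD8 C4 day 2 (-2.26; gap 0.561 of the range), the mitochondrial list on TMD8 D7 day 2 (median -0.11; gap 0.595) and the number of outlier spots on HBL1 D7 day 2 (436; gap 0.673).

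Of the genes named for the mean, these differed between TMD8 and HBL1 by the limma test, with TMD8 minus HBL1 log2 values of 0.479 for CD52, -1.296 for HLA-DPB1, -0.469 for ALDH2, -1.11 for HLA-DPA1, -0.944 for HLA-DRA, 0.454 for TLR9, 0.945 for GZMB and -1.027 for VSNL1. Lists that differed between lines by camera had mean differences of 0.259 for NF-kB targets, 0.301 for interferon, 0.27 for immediate early genes, -0.061 for the unfolded protein response, 0.145 for p53 targets, -0.25 for MHC class II, 0.082 for heat shock, 0.105 for ribosomal proteins and 0.322 for histones. Lists that differed between days by camera had day 2 minus day 1 means of 0.107 for the TLR pathway, 0.094 for NF-kB targets, 0.246 for interferon, 0.135 for BCR components, -0.109 for MYC targets, -0.128 for G1/S, -0.062 for G2/M, 0.078 for p53 targets, 0.168 for B cell identity, 0.256 for MHC class II, 0.078 for apoptosis regulators, -0.049 for heat shock and -0.136 for histones. None of these list differences held with an estimated correlation, with adjusted p from 0.358 to 0.751 for lines and 0.144 to 0.756 for days.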

How the results depend on the processing

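The base composition correction was chosen after the results were seen, and the other alternatives before. TLR9 kept its fall over both lines under every alternative run (-1.46 to -1.08), and its call in HBL1 was lost with median centring (-1.45). Named genes kept their call and direction, or stayed uncalled in either direction, in 1721 settings. They lost the call in 113, gained it in 3 and reversed in 0. Direction was not compared where a result was uncalled both times. For gene lists, by the direction of the set test, these numbers were 2523, 104, 79 and 21.

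Median centring moved the gene counts most, with 1376 genes for the mean, 371 in TMD8, 10 in HBL1, 1 between lines and 0 between hairpins (limma, 354 unadjusted). It leaves a trend of ratio with intensity (r from -0.41 to 0.86 over arrays, against -0.03 to 0.03 after loess). Under it the direction of these lists by camera turned, with means on average of G1/S 0.204, cholesterol 0.24, histones 0.253, mitochondrial 0.405 and myeloid -0.002; between lines ABC signature 0.294, G2/M 0.282, mitochondrial 0.332, plasma cell 0.282 and unfolded protein response 0.188; between hairpins BCR components 0.081, ribosomal 0.25, MYC 0.246, TLR 0.202 and unfolded protein response 0.111; between days ABC signature -0.173, BCR components -0.031, ribosomal -0.26 (-0.092 with scaling between arrays), germinal centre -0.179 and p53 -0.07. For these called lists the mean changed sign and the call ended while camera's direction stayed: on average MYC 0.109 and ATF4 0.044; between lines MHC class II 0.047; between hairpins B cell identity 0.006; between days TLR -0.018, NF-kB -0.028 and apoptosis -0.041.

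The remaining causes were not tested. Line differences numbered 915 with offset 10, 687 with deposited log ratios, 743 with the authors' value table and 570 with no hairpin and day terms. Hairpin differences numbered 750, 442 and 363 with the first 3 of these and 2415 with an interaction term. Correlations were 0.418 (hairpins) and 0.545 (lines) with deposited log ratios, 0.482 (lines) with the value table, 0.654 (lines) with the strict filter, 0.615 (hairpins) over genes past the threshold in the other line and 0.405 for C4 of 1 line against D7 of the other. The day test called 1 gene with the strict filter, with a trended robust spread or with the block. With an estimated correlation 0 lists were called on average, and fry called 13 on average, 5 between lines, 4 between hairpins and 0 between days. Averaging hairpins per line and day left 4 values, and 5066, 4982 and 460 genes for TMD8, HBL1 and lines.

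With line and day as a block (correlation -0.28) the counts were 12467 for the mean, 9964 in TMD8, 9644 in HBL1, 3263 between lines, 803 between hairpins and 1 between days. A negative correlation lowers the error of all these tests but that of the hairpins. Their larger counts thus make no allowance for shared controls. Numbered arrays share only accession order and day, so no further pairing was tested. Leaving out single arrays gave 8814 to 9763 genes for the mean, 4742 to 7722 in TMD8, 4946 to 8001 in HBL1, 604 to 1067 between lines, 374 to 885 between hairpins and 10 to 13 lists; fewer arrays also leave fewer degrees of freedom. The planned slide block equals the line term and was not run apart from it, and camera takes no block. Base composition correction left 10738, 7866, 7776, 1618, 1588 and 0 genes for the mean, TMD8, HBL1, line, hairpin and day, and 11 lists. Signal over background limits probes dim in 1 channel, as for PTGDR and CR1L.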

Other observations

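None of the tests in this part was chosen after its result was seen, but the 19 genes below were picked after their values were seen. Genes that changed by over 1.5-fold in each of the 4 line and hairpin pairs numbered 19, with 15 higher and 4 lower. Those higher included CD52, ALDH2, HLA-DMA, a chaperone of MHC class II peptide loading, ALOX5AP, the partner of 5-lipoxygenase in leukotriene synthesis, and ARHGAP9. ACTB (0.714 to 0.971 over the pairs), OAZ1 (0.645 to 0.835) and RPS27 (0.636 to 0.701) were also among them. For rises so alike in all pairs, a dye effect or an effect of the control hairpin shared by all arrays stays open. The 4 lower were TLR9, GZMB, SOCS3 and GPRC5B.

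Other lists that camera did not call on average held single genes that passed in limma. BCL2, the antiapoptotic gene, rose by 0.64 (0.08 by a second probe) and FAS by 0.36, with 13 higher and 6 lower of 30 apoptosis regulators (15 and 6 adjusted over the list alone; camera adjusted p = 0.248). BATF fell by 0.58 and LGALS1 rose by 0.59, with 7 higher and 11 lower of 30 targets of IL-10, IL-6 and STAT3 (7 and 12 adjusted over the list alone; camera adjusted p = 0.159). IRF4, a transcription factor of plasma cells that ABC lymphoma lines depend on, fell by 0.66. Of 24 plasma cell genes 8 were higher and 8 lower (9 and 8 adjusted over the list alone; camera adjusted p = 0.865). The ABC lymphoma signature had 10 higher and 11 lower of 30 (10 and 12 adjusted over the list alone; camera adjusted p = 0.248). ITPKB rose by 0.53 (0.16 by a second probe), with 10 higher and 3 lower of 24 germinal centre genes (10 and 4 adjusted over the list alone; camera adjusted p = 0.123). SGK1 and ATF3 (-0.80) fell, with 11 higher and 12 lower of 38 immediate early genes (11 and 12 adjusted over the list alone; camera adjusted p = 0.38).

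CDC25B rose by 0.28, and KIF11 was at -0.31 by the probe used and at 0.08 (adjusted p = 0.0367) by another, with 20 higher and 9 lower of 40 G2/M genes (the same adjusted over the list alone; camera adjusted p = 0.377). SLC16A3, a lactate exporter gene, rose by 0.76, with 7 higher and 12 lower of 31 glycolysis and hypoxia genes (10 and 12 adjusted over the list alone; camera adjusted p = 0.248). TP53I3 rose by 0.42 and AEN fell by 0.37, with 11 higher and 5 lower of 29 p53 targets (13 and 6 adjusted over the list alone; camera adjusted p = 0.292). SYVN1 rose by 0.31, with 10 higher and 3 lower of 29 unfolded protein response genes (10 and 3 adjusted over the list alone; camera adjusted p = 0.585). HSPA4L fell by 0.53, with 2 higher and 8 lower of 24 heat shock genes (the same adjusted over the list alone; camera adjusted p = 0.0568). SDHB fell by 0.22, with 4 higher and 5 lower of 21 mitochondrial and respiratory chain genes (3 and 5 adjusted over the list alone; camera adjusted p = 0.511). With median centring the mean of the mitochondrial list turned from -0.01 to 0.41.

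The control channel of TMD8 C4 day 2 stood apart. The SD of its log2 difference from the other TMD8 controls was 0.254 to 0.266, against 0.122 to 0.156 among the others, and its array weight was the lowest, at 0.526.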
